A study of Mus musculus and Homo sapiens with 171 samples.

How the data were processed

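Gene-level RNA-seq values of 171 samples were taken from 10 deposited tables with 176 columns, 5 samples standing in 2 tables. The submitters' processing notes name TRIzol extraction, reverse transcription of polyadenylated RNA, ligation of an adaptor at the 3′ end and amplification by PCR, followed by trimming with Trimmomatic 0.39 and alignment with HISAT2 to mm10 or hg38. The HISAT2 version, the program that counted reads and the gene annotation were not given in the sources used here. The deposited tables held CPM (counts scaled to a fixed total per sample) by the authors, with no correction for gene length. This unit was checked in every column. The columns summed to the scale of that unit, and low values were whole multiples of 1 step to within 0.25 of a read, in 100% of values except in the first replicate without Dox at 12 h of the FLII line, with 81.7%. The step gave the depth of each sample. Read numbers were recovered in 136 samples, and in the other 35 the rounding of the deposited values was too coarse. Each mouse table listed 24982 genes, of which 98.2% matched the annotation used for positions, and 28130 genes stood in the human table.

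Groups were taken from the sample labels, with the DGCR8, FLII or JUN genotype, siRNA, Dox, inhibitor, time and replicate number. A sample of FLII KO mESCs also served as day 0 of the FLII KO embryoid bodies. Replicates were kept as separate samples, since the lowest chi-square per degree of freedom between any pair was 2.53, or 1.26 if reads came in pairs. Outside the knockout table replicates 2 and 3 were the closest pair in 33 of 39 groups, with a median chi-square per degree of freedom of 3.49 against 12.1 for pairs with replicate 1. The third Dicer KO replicate is labelled as a reanalysis of a library from another series. In 7 libraries of the knockout table, 2 each of wild type and DGCR8 KO and all 3 of Dicer KO, 54.9 to 58.4% of low read numbers were even, against 75.0 to 90.6% in 129 others.

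For each table log2(CPM + 1) of the groups with n = 3 was fitted with limma 3.58.1 (empirical Bayes with trend) in R 4.3.3, with 1 coefficient per group. The knockout table was fitted in 3 parts, the wild type with the DGCR8, FLII and double KO, the wild type with the Dicer KO, and the rescues. In all, 25 comparisons of groups and 7 differences or interactions were tested. Genes with at least 1 CPM in at least 3 samples of the fit were tested. The p-values were adjusted by the Benjamini-Hochberg method within a comparison, with a threshold of 0.05. Dox effects in EpiLCs were averaged over the times with n = 3. The comparisons, the first set of alternatives and the rule for named genes were, like the gene lists, chosen before the data were examined. Lists were tested with camera at its preset correlation of 0.01, with p-values adjusted over the lists of at least 3 measured genes. The same test was repeated with a correlation estimated from the residuals. Named genes were the targeted genes, a panel of 8 immediate-early genes, up to 6 of the immediate-early list and 4 of each other list with the largest changes past the threshold, and the 4 highest and 4 lowest past the threshold whose higher group mean was at least 5 CPM, whose groups did not overlap and whose symbol was not a predicted or clone name. Groups with n = 1 were compared as differences of log2(CPM + 1) without a test, with the percentile of a list's median among 10000 random lists matched on expression.

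The calls were tested on simulated data made from the deposited values with known changes. In FLII KO against wild-type mESCs, changes of 1.5-fold, 2-fold and 4-fold were recovered in 5.97, 22.4 and 84.8% of genes, and in the FLII Dox comparison in 94.0, 98.5 and 100%. The alternatives were a pseudocount of 0.1, no filter, quantile normalization, fits of the compared groups alone, the replicate number as a block and leaving out each replicate. Alternatives added later were averaging replicates 2 and 3, a term for the share of even read numbers in the knockout table, leaving out chromosomes with shifted medians, leaving out 1 time from the Dox averages, and edgeR 4.0.16 with TMM scaling on recovered reads. Replicate numbers paired the samples in 5 of 32 comparisons, judged by a correlation over 0.1 in every pair. Chromosome medians used gene positions in mm10, and human samples were not examined by chromosome. A result that needs an item withheld for evaluation is not reported.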

Results

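Transcript levels were measured by RNA-seq in 171 samples, 159 from mouse embryonic stem cells (mESCs) or cells differentiated from them and 12 from human naive embryonic stem cells of the established WIBR3 line. The samples fell into 77 groups, of which 47 held 3 replicates and 30 held 1. Knockout lines covered DGCR8, the RNA-binding partner of DROSHA in the Microprocessor complex that cuts primary microRNA transcripts, FLII, an actin-binding gelsolin-family protein, both genes together, Dicer, which cuts microRNA precursors, and JUN, a subunit of the AP-1 transcription factor. Doxycycline (Dox) was given to KH2 lines made to express DGCR8, FLII or JUN, siRNAs were aimed at DGCR8, FLII or DROSHA, and PD0325901 inhibited MEK, the kinase above ERK. No KH2 line without a transgene was given Dox, so Dox itself cannot be told apart from the expressed gene in the Dox comparisons. The cells were sampled as mESCs, as epiblast-like cells (EpiLCs) at 0, 6, 12, 24 and 48 h of differentiation, or as embryoid bodies at days 0, 1, 4 and 8. Depth ran from 3.03 to 54.2 M counted reads (M, 10⁶) per sample, with a median of 16.9 M. By experiment the ranges in M reads were 4.02 to 43.0 for knockout and rescue lines, 6.11 to 25.4 for mouse siRNAs, 3.03 to 21 for human siRNAs, 8.76 to 52.1 for knockout EpiLCs, 9.67 to 54.2 for FLII Dox, 5.97 to 29.5 for JUN Dox, 9.01 to 28.7 for MEK inhibition of EpiLCs, 5.05 to 35.2 for FLII KO embryoid bodies, 9.78 to 30.4 for DGCR8 Dox embryoid bodies and 22.0 to 30.4 for embryoid bodies with MEK inhibitor.

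Levels were expressed as CPM, counts scaled to 10⁶ per sample, and are given as mean ± SD with n = 3 per group unless another n stands beside them. Values in parentheses after a gene are the log2 fold change ± SE from limma on log2(CPM + 1), first group against second, and every gene described as having risen, fallen or changed had an adjusted p under 0.05. The pseudocount of 1 understates fold changes of genes near or under 1 CPM. Gene lists were fixed before the data were examined, the adjusted p after a list's median is that of camera with its preset correlation, and 92 of 222 such calls held with an estimated correlation. Where quantile scaling shifted the median of all genes by over 0.1, list medians are given relative to that of all genes and called relative. Nothing in the records says that replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

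Targeted genes came first. Dgcr8 (mm10 chromosome 16, 18253948 to 18289246) stood at 22.6 ± 0.376 CPM in DGCR8 KO and 26.8 ± 5.33 CPM in double KO mESCs against 88.5 ± 1.27 CPM in wild type, so that transcript remained in the knockout. Flii (chromosome 11, 60714123 to 60727263) stood at 18.8 ± 2.26 CPM in FLII KO and 18.1 ± 15.5 CPM in double KO cells against 80.4 ± 4.18 CPM. Double KO replicate 3 stood apart, with Flii at 36.0 CPM against 8.02 and 10.2 CPM and a root mean square log2 difference of 0.92 and 0.91 from the other libraries, which differed by 0.19. In EpiLCs, Flii was 14.6 ± 0.445 CPM at 6 h and 16.1 ± 2.28 CPM at 48 h in FLII KO cells against 82.6 ± 7.10 and 77.6 ± 0.682 CPM in wild type. Embryoid bodies of the same genotype held 15.8 ± 1.02 CPM at day 1 and 20 ± 2.89 CPM at day 4 against 77.1 ± 2.52 and 104 ± 2.79 CPM. Dicer1 (chromosome 12, 104687742 to 104751952) fell from 158 ± 12.5 to 26.6 ± 2.62 CPM in Dicer KO cells. Jun (chromosome 4, 95049034 to 95052222) was 3.59 ± 1.25 CPM at 6 h and 3.39 ± 1.01 CPM at 48 h in JUN KO EpiLCs against 7.64 ± 1.36 and 39.4 ± 2.15 CPM.

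Dox raised Flii in EpiLCs to 501 ± 154 CPM at 6 h, 1156 ± 7.63 CPM at 12 h and 925 ± 147 CPM at 48 h, against 59.8 ± 3.21, 51.9 ± 2.99 and 62.6 ± 3.37 CPM without it. Jun reached 1048 ± 42.3 CPM at 6 h and 229 ± 32.9 CPM at 48 h against 6.91 ± 0.849 and 5.17 ± 1.32 CPM. The DGCR8 line responded far less at the level of its transcript, with Dgcr8 at 103 ± 7.68 against 74.9 ± 2.60 CPM at day 1 and 67.5 ± 3.47 against 71.6 ± 4.27 CPM at day 4. In double KO rescue lines, Flii and Dgcr8 were 1128 ± 466 and 30.5 ± 3.06 CPM with FLII alone. With DGCR8 added they were 1449 ± 329 and 40.4 ± 6.37 CPM. With DGCR8 lacking its RNA-binding domain (RBD) they were 1840 ± 212 and 27.8 ± 3.76 CPM. The siRNA against DGCR8 left 43.8 ± 1.5 CPM of Dgcr8 in mouse cells and 27.4 ± 0.779 CPM of DGCR8 in human cells, against 69.3 ± 3.22 and 76.4 ± 5.43 CPM with control siRNA (siNC). With siDGCR8 and siFLII combined, the same transcript stood at 70.5 ± 1.45 CPM in mouse cells and 42.1 ± 4.23 CPM in human cells. FLII siRNA lowered Flii to 25.6 ± 3.5 CPM and FLII to 26.6 ± 1.98 CPM, and DROSHA siRNA lowered Drosha to 57.4 ± 2.72 CPM and DROSHA to 26.9 ± 3.37 CPM.

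**Figure D1:**
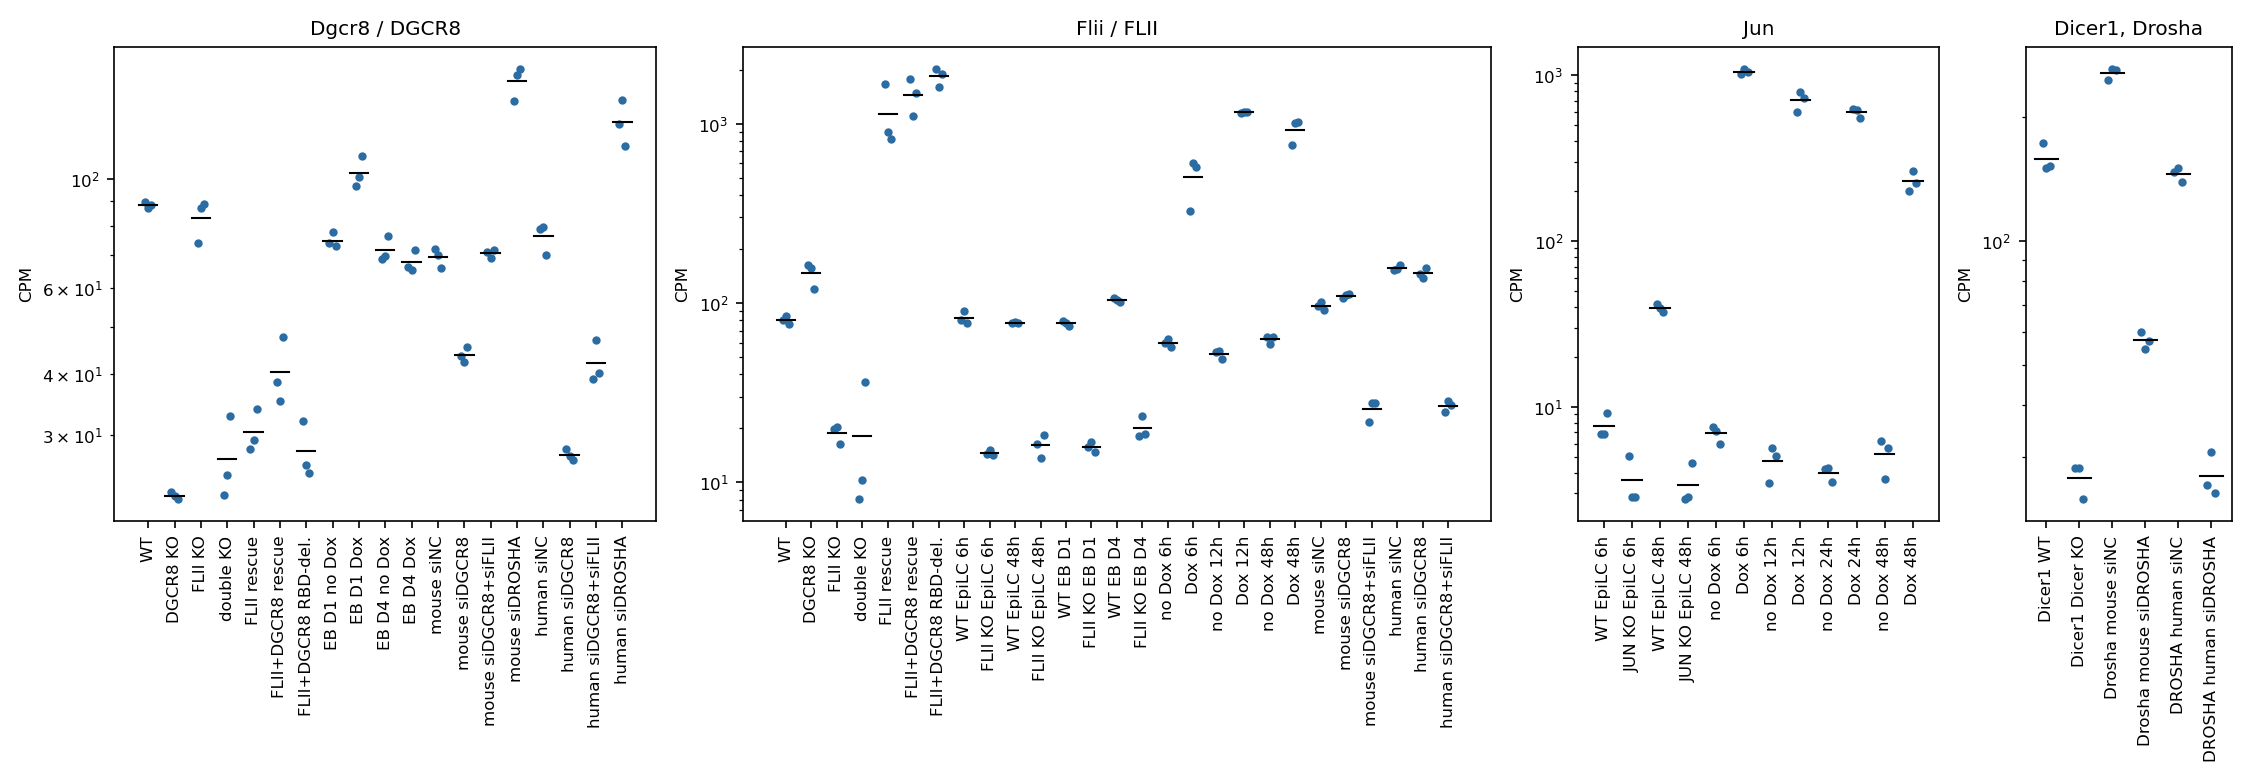
CPM of Dgcr8, Flii, Jun, Dicer1 and Drosha or their human orthologues (log axis) in each library of the groups that target them and of their controls, 1 point per library and a bar at the group mean. Dgcr8 with siDGCR8 and siFLII combined in mouse cells lies at the level of the control siRNA, and Flii and Jun under Dox lie above every control library.

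DGCR8 KO was set against wild-type mESCs to ask which transcripts, immediate-early genes among them, depend on DGCR8. Among targets of the miR-290 and miR-302 families the Hippo kinase Lats2 (2.86 ± 0.29), Casp2 (2.32 ± 0.16) and the retinoblastoma-family gene Rbl2 (2.08 ± 0.20) rose. In the miR-290 and miR-302 target list 7 of 9 members rose and 1 fell (7 and 1 adjusted over the list alone, relative median 1.13, adjusted p = 0.0687), and by quantile scaling the adjusted p was 0.0263. The primary microRNA transcripts Mir17hg (2.26 ± 0.24) and Mirg (2.49 ± 0.27) rose. In the primary microRNA list 3 of 7 members rose and 2 fell (3 and 2 adjusted over the list alone, relative median 0.19, adjusted p = 0.867). Among immediate-early genes, which are transcribed within minutes of a stimulus, Atf3 (2.94 ± 0.42), Jun (1.66 ± 0.39), Fos (1.57 ± 0.24), Rhob (2.89 ± 0.25) and Gadd45b (1.72 ± 0.31) rose, whereas Myc (1.44 ± 1.06 against 152 ± 26.4 CPM, −6.04 ± 0.27) and Egr3 (−2.29 ± 0.66) fell. Of the immediate-early list 11 of 36 members rose and 10 fell (11 and 10 adjusted over the list alone, relative median −0.09, mean 0.03, test pointing down, adjusted p = 0.821). The endoderm-associated genes Cubn (−3.86 ± 0.49), Dab2 (−3.58 ± 0.44) and Lama1 (−2.72 ± 0.30) fell. In the extraembryonic endoderm list 1 of 11 members rose and 8 fell (1 and 8 adjusted over the list alone, relative median −1.84, adjusted p = 7.7e-04, adjusted p = 0.379 with an estimated correlation). The ERK feedback genes Spry4 (−3.43 ± 0.47), Etv4 (−3.41 ± 0.27) and Dusp6 (−2.21 ± 0.39) fell as well. In the ERK output list 1 of 12 members rose and 6 fell (1 and 6 adjusted over the list alone, relative median −0.70, adjusted p = 0.0867). The naive pluripotency factor Klf2 (3.30 ± 0.30) and the formative factors Zic2 (3.97 ± 0.30) and Otx2 (3.34 ± 0.48) rose and the RNA-binding protein Lin28a (−3.29 ± 0.31) fell. Of 13790 genes tested, 4570 rose and 2909 fell. Quantile scaling moved the median of all genes by −0.24 and the share of changed genes that rose from 61.1% to 47.3%. Taken without reference to all genes, the median of the immediate-early list was 0.09, but −0.03 under that scaling and −0.08 without DGCR8 KO replicate 3.

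Loss of FLII alone was compared with wild type in the same way. Immediate-early transcripts stood lower, with Egr1 (−1.99 ± 0.68, adjusted p = 0.334), which encodes a zinc-finger factor of the early growth response, Junb (−0.81 ± 0.33, adjusted p = 0.39) and Fos (−0.64 ± 0.24, adjusted p = 0.370), none of them past the threshold. Of the immediate-early list 0 of 36 members rose and 0 fell (0 and 0 adjusted over the list alone, median −0.32, adjusted p = 0.0129, adjusted p = 0.703 with an estimated correlation). The core pluripotency list lay higher, and 0 of 8 members rose and 0 fell (0 and 0 adjusted over the list alone, median 0.38, adjusted p = 0.00191, or 0.0821 with an estimated correlation). For the formative list, of genes active between the naive and primed states, 0 of 10 members rose and 0 fell (1 and 0 adjusted over the list alone, median 0.35, adjusted p = 0.0129, adjusted p = 0.468 with an estimated correlation). Flii (−2.04 ± 0.39, adjusted p = 0.172) itself missed the threshold although its groups stood far apart. By limma 0 genes of 13790 rose and 1 fell, the keratin Krt13 (−1.5 ± 0.17), whereas edgeR called 0 genes, with 1557 at an unadjusted p under 0.05. Simulated 2-fold changes were recovered in 22.4% of genes. Without FLII KO replicate 2 or wild-type replicate 3 the count became 56 or 5 and the list's adjusted p 0.111 or 0.831, and leaving out FLII KO replicate 1 or wild-type replicate 1 or 2 left 0 genes.

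Double KO cells were compared with wild type and with DGCR8 KO cells to ask what loss of FLII adds where DGCR8 is absent. Against wild type, the miR-290 and miR-302 targets were higher, with Lats2 (3.02 ± 0.29) and Casp2 (1.74 ± 0.16). Of 9 miR-290 and miR-302 target genes, 6 rose and 1 fell (6 and 1 adjusted over the list alone, median 0.92, adjusted p = 0.00237, adjusted p = 0.149 with an estimated correlation). Interferon-response genes rose, among them the antiviral Ifitm3 (2.80 ± 0.22) and Oas1a (3.25 ± 0.38). In the interferon list 9 of 13 members rose and 0 fell (10 and 0 adjusted over the list alone, median 2.00, adjusted p = 9.5e-06, adjusted p = 0.149 with an estimated correlation). The extraembryonic endoderm list fell. Of 11 extraembryonic endoderm genes, 0 rose and 10 fell (0 and 10 adjusted over the list alone, median −2.82, adjusted p = 3.0e-06, adjusted p = 0.149 with an estimated correlation) and Lama1 (8.72 ± 3.19 against 325 ± 25.1 CPM, −5.12 ± 0.30) by most. Of the immediate-early list 3 of 36 members rose and 9 fell (3 and 8 adjusted over the list alone, median −0.06, adjusted p = 0.918), and Jun (0.26 ± 0.39, adjusted p = 0.617) and Fos (0.29 ± 0.24, adjusted p = 0.356) did not pass. In all, 2461 genes of 13790 rose and 3163 fell, and without the deviating replicate 3 of double KO 6435 changed. The list's median was 0.27 without wild-type replicate 3 and 0.06 without the chromosomes whose genes were shifted as a whole.

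Against DGCR8 KO cells, Atf3 (5.06 ± 4.58 against 23.8 ± 6.06 CPM, −2.27 ± 0.42), Jun (−1.40 ± 0.39) and Fos (−1.28 ± 0.24) fell, as did Ier3 (−1.41 ± 0.39), while Myc (3.84 ± 0.27) rose. In the immediate-early list 5 of 36 members rose and 11 fell (5 and 11 adjusted over the list alone, relative median 0.04, mean −0.18, test pointing up, adjusted p = 0.764). The ERK feedback genes Etv4 (2.13 ± 0.27), Spry4 (2.10 ± 0.47) and Dusp6 (1.76 ± 0.39) rose. Of 12 ERK output genes, 6 rose and 2 fell (6 and 2 adjusted over the list alone, relative median 0.94, adjusted p = 0.0663). Of the integrated stress response, which is induced when translation is curbed, Chac1 (−2.74 ± 0.54), Ddit3 (−1.75 ± 0.29) and Ddit4 (−2.32 ± 0.45) fell. In the integrated stress list 1 of 14 members rose and 7 fell (1 and 7 adjusted over the list alone, relative median −0.45, adjusted p = 0.276). Basement membrane genes fell in company, with Fn1 (−1.59 ± 0.17), Col4a2 (−1.61 ± 0.23) and Nid1 (−1.48 ± 0.26). In the basement membrane list 0 of 10 members rose and 9 fell (0 and 9 adjusted over the list alone, relative median −0.80, adjusted p = 0.0390, adjusted p = 0.744 with an estimated correlation). Of 13790 genes 2216 rose and 5030 fell, and quantile scaling moved the median of all genes by 0.33 and the share that rose from 30.6% to 55.0%. With a term for the 2 kinds of library in this experiment the count was 4675, and without double KO replicate 3 7852. Tested directly as an interaction, the effect of losing FLII differed between DGCR8 KO and wild-type backgrounds for 3749 genes, 1313 upward and 2436 downward. Of the ERK output list 6 of 12 members rose and 0 fell (6 and 1 adjusted over the list alone, relative median 1.03, adjusted p = 0.0225, adjusted p = 0.691 with an estimated correlation, adjusted p = 0.0640 by quantile scaling). Of 36 immediate-early genes, 5 rose and 3 fell (3 and 0 adjusted over the list alone, relative median 0.22, adjusted p = 0.275). The median of all genes moved by 0.26 under quantile scaling and the upward share from 35.0% to 60.4%. The count fell to 0 without the libraries numbered 1 and to 0 without those numbered 2, and rose to 5688 without those numbered 3.

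Dicer KO cells, lacking mature microRNAs with the Microprocessor intact, were compared with wild type. The miR-290 and miR-302 targets Lats2 (3.39 ± 0.21), Cdkn1a (2.28 ± 0.15), a cell cycle inhibitor, and Casp2 (1.81 ± 0.16) rose. The miR-290 and miR-302 target list had 6 of 9 members that rose and 1 that fell (6 and 1 adjusted over the list alone, median 1.21, adjusted p = 0.0341, adjusted p = 0.420 with an estimated correlation). Primary microRNA transcripts did not rise with them: Mirg (−2.74 ± 0.19) and H19 (−2.69 ± 0.52) fell. Of 7 primary microRNA genes, 1 rose and 5 fell (1 and 5 adjusted over the list alone, median −1.77, adjusted p = 0.0447, adjusted p = 0.430 with an estimated correlation, adjusted p = 0.0754 by quantile scaling). Jun (44.0 ± 4.11 against 11.4 ± 2.66 CPM, 1.88 ± 0.20) rose and Junb (−1.34 ± 0.31), Myc (−4.67 ± 0.30) and Egr3 (−2.28 ± 0.76) fell among immediate-early genes. The immediate-early list had 9 of 35 members that rose and 11 that fell (9 and 11 adjusted over the list alone, median −0.10, adjusted p = 0.816). ERK output genes fell, with Etv4 (−3.74 ± 0.20) and Spry4 (−2.74 ± 0.32). The ERK output list had 1 of 12 members that rose and 7 that fell (1 and 7 adjusted over the list alone, median −0.91, adjusted p = 0.0447, adjusted p = 0.542 with an estimated correlation, adjusted p = 0.0834 by quantile scaling). Of 13105 genes 3699 rose and 3486 fell. The third Dicer library came from another series, and without it 7448 genes changed. The immediate-early median was 0.01 without wild-type replicate 2, 0.20 without replicate 3 and 0.18 with a term for kind of library. By the correlation rule the numbers paired the libraries here, but nothing links the third Dicer library with wild-type replicate 3. These libraries also differed in kind, with 55.4 and 86.8% even read numbers. With replicate as a block the count was 7774 and the list's adjusted p 0.769, a fit that treats them as a pair.

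Rescue lines asked what DGCR8, whole or without its RBD, adds to FLII, though mean Flii also differed. With whole DGCR8, Lin28a (198 ± 28.2 against 3.06 ± 1.45 CPM, 5.67 ± 0.24) and Myc (3.31 ± 0.29) rose, and the miR-290 and miR-302 targets fell without exception, with Tgfbr2 (−2.06 ± 0.19), Cdkn1a (−1.58 ± 0.12), Rbl2 (−1.35 ± 0.15) and Lats2 (−1.26 ± 0.16). Across 8 miR-290 and miR-302 target genes, 0 rose and 8 fell (0 and 8 adjusted over the list alone, relative median −0.96, adjusted p = 3.1e-05, adjusted p = 0.201 with an estimated correlation). Immediate-early genes Fos (−1.16 ± 0.41), Ccn1 (−1.21 ± 0.28), a matricellular protein, Rhob (−1.23 ± 0.25), Atf3 (−0.89 ± 0.17) and Jun (−0.66 ± 0.23) fell. Across 33 immediate-early genes, 3 rose and 15 fell (3 and 15 adjusted over the list alone, relative median −0.27, adjusted p = 0.187). Cytoskeletal targets of serum response factor (SRF) fell, with Acta1 (−1.76 ± 0.28) and Tpm1 (−1.22 ± 0.12). In the SRF target list 1 of 15 members rose and 11 fell (1 and 11 adjusted over the list alone, relative median −0.39, adjusted p = 0.00817, adjusted p = 0.495 with an estimated correlation). Of 12994 genes 2105 rose and 3578 fell, the median of all genes moved by 0.12 under quantile scaling and the share that rose from 37.0% to 50.8%. Without FLII rescue replicate 3 the immediate-early list had an adjusted p of 0.0375.

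In the RBD-deletion rescue 217 genes rose and 317 fell, but Dgcr8 was no higher there than with FLII alone, so the values do not show that the construct was expressed. No gene of the miR-290 and miR-302 target list passed. In the miR-290 and miR-302 target list 0 of 8 members rose and 0 fell (0 and 2 adjusted over the list alone, median 0.06, mean −0.09, test pointing up, adjusted p = 0.990), whereas the keratins Krt8 (−1.64 ± 0.19), Krt18 (−1.53 ± 0.35) and Krt7 (−1.41 ± 0.33) fell, with Ier3 (−1.22 ± 0.23), Plaur (−1.34 ± 0.11), an AP-1 target, and Myc (−1.30 ± 0.29). Of the immediate-early list 0 of 33 members rose and 2 fell (0 and 2 adjusted over the list alone, median −0.27, adjusted p = 0.0116, adjusted p = 0.757 with an estimated correlation). The ERK output list lay lower. Across 12 ERK output genes, 0 rose and 3 fell (0 and 6 adjusted over the list alone, median −0.26, adjusted p = 0.0285, adjusted p = 0.757 with an estimated correlation). The count was 272 without the filter on low values, 201, 123 and 176 without RBD-deletion replicates 1, 2 and 3, and 344 without FLII rescue replicate 2, and the immediate-early list's adjusted p was 0.181 without FLII rescue replicate 1. Set against each other, whole DGCR8 gave more Lin28a (4.86 ± 0.24) and Myc (4.61 ± 0.29) than the deletion and less Cdkn1a (−1.52 ± 0.12), Tgfbr2 (−1.46 ± 0.19) and Rbl2 (−1.42 ± 0.15). Of 8 miR-290 and miR-302 target genes, 0 rose and 8 fell (0 and 8 adjusted over the list alone, median −0.89, adjusted p = 4.1e-05, adjusted p = 0.238 with an estimated correlation). The ERK output genes Etv4 (1.75 ± 0.15) and Spry4 (1.35 ± 0.18) were higher with whole DGCR8. In the ERK output list 7 of 12 members rose and 0 fell (7 and 0 adjusted over the list alone, median 0.37, adjusted p = 0.00165, adjusted p = 0.729 with an estimated correlation). Of the immediate-early list 7 of 33 members rose and 11 fell (7 and 12 adjusted over the list alone, median −0.05, mean 0.01, test pointing down, adjusted p = 0.987), and Fos (−0.26 ± 0.41, adjusted p = 0.629) and Jun (−0.26 ± 0.23, adjusted p = 0.372) did not pass, while Ccn1 (−0.88 ± 0.28) and Atf3 (−0.65 ± 0.17) were lower. That median turned to 0.02 without the filter on low values, 0.01 without the chromosomes whose genes were shifted as a whole, and 0.01 without replicate 2 of the whole rescue or replicate 1 of the deletion. In total 2592 genes rose and 3585 fell.

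Knockdown by siRNA in mESCs asked which effects of DGCR8 loss appear without a knockout line. The primary microRNA transcripts Mir22hg (21.5 ± 1.94 against 3.70 ± 0.380 CPM, 2.26 ± 0.14) and Mirg (1.26 ± 0.21) rose. The primary microRNA list had 5 of 7 members that rose and 0 that fell (5 and 0 adjusted over the list alone, relative median 0.51, adjusted p = 0.00206). The immediate-early genes Ccn1 (1.52 ± 0.10), Gadd45b (1.06 ± 0.11), Jun (0.52 ± 0.11) and Btg2 (0.97 ± 0.07) rose while Myc (−1.43 ± 0.09), Ier3 (−0.83 ± 0.18) and Egr1 (−0.46 ± 0.16) fell. In the immediate-early list 13 of 35 members rose and 5 fell (14 and 5 adjusted over the list alone, relative median 0.12, adjusted p = 0.0569). Targets of p53 rose, with Ccng1 (1.17 ± 0.08) and Cdkn1a (1.30 ± 0.08). In the p53 target list 9 of 13 members rose and 1 fell (9 and 1 adjusted over the list alone, relative median 0.42, adjusted p = 1.3e-05). Glycolysis genes fell, with Pfkp (−1.51 ± 0.06), Ldha (−1.30 ± 0.05) and Pgk1 (−1.21 ± 0.05). In the glycolysis list 1 of 14 members rose and 12 fell (1 and 12 adjusted over the list alone, relative median −0.88, adjusted p = 9.0e-19). The keratins Krt18 (1.57 ± 0.08) and Krt8 (1.15 ± 0.08), shared by trophectoderm and other epithelia, rose. In the trophectoderm list 5 of 9 members rose and 0 fell (5 and 0 adjusted over the list alone, relative median 0.86, adjusted p = 0.00105, adjusted p = 0.114 with an estimated correlation). Of 13128 genes 2750 rose and 1513 fell, with a shift of the median by −0.11 under quantile scaling and a share that rose of 48.4% in place of 64.5%. The immediate-early list passed in 4 alternatives, with an adjusted p of 0.0349 without the filter, 0.0459 by quantile scaling, 0.0199 without siDGCR8 replicate 1 and 0.0347 without siNC replicate 2, and the count was 2447 with replicates 2 and 3 averaged.

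Adding siFLII to siDGCR8 asked what FLII contributes once DGCR8 is lowered, although Dgcr8 itself was back at the level of siNC. Ccn1 (−0.43 ± 0.10), Gadd45b (−0.72 ± 0.11) and Sik1 (−0.83 ± 0.07) fell and Myc (2.22 ± 0.09) rose among immediate-early genes, while Jun (−0.17 ± 0.11, adjusted p = 0.222) and Fos (−0.19 ± 0.28, adjusted p = 0.618) did not pass. Of 35 immediate-early genes, 7 rose and 7 fell (6 and 7 adjusted over the list alone, relative median 0.05, adjusted p = 0.626). Cdkn1a (−1.18 ± 0.08) fell, as did Bbc3 (−1.07 ± 0.14), a p53 target, and Ddit3 (−1.41 ± 0.18), of the stress response. Of 13 p53 target genes, 0 rose and 8 fell (0 and 9 adjusted over the list alone, relative median −0.25, adjusted p = 0.0440, adjusted p = 0.469 with an estimated correlation). Basement membrane genes fell, with Fn1 (−0.63 ± 0.05) and Nid1 (−0.44 ± 0.06). Of 10 basement membrane genes, 0 rose and 9 fell (0 and 10 adjusted over the list alone, relative median −0.23, adjusted p = 6.3e-05, adjusted p = 0.130 with an estimated correlation). Of 13128 genes 2013 rose and 3427 fell, the median of all genes shifted by 0.10 under quantile scaling and the share that rose from 37.0% to 50.9%. The count was 3619 with replicates 2 and 3 averaged. The immediate-early median, −0.03 without reference to all genes, was 0.00 in that setting and also without siDGCR8 replicate 2, and 0.06 by quantile scaling.

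DROSHA knockdown lowered the catalytic subunit of the same complex but, with Dgcr8 raised, does not isolate DGCR8 loss. Dgcr8 (1.18 ± 0.07) rose, and the primary microRNA transcripts rose with it, as Mir22hg (2.14 ± 0.14), Mir17hg (1.61 ± 0.12) and Mirg (1.58 ± 0.21) show. Across 7 primary microRNA genes, 5 rose and 0 fell (5 and 0 adjusted over the list alone, median 0.83, adjusted p = 8.0e-06). Among immediate-early genes Gadd45b (0.62 ± 0.11), Ccn1 (0.58 ± 0.10) and Junb (0.39 ± 0.10) rose and Jun (0.24 ± 0.11, adjusted p = 0.0875) and Fos (−0.24 ± 0.28, adjusted p = 0.540) did not pass. The immediate-early list had 6 of 35 members that rose and 5 that fell (6 and 5 adjusted over the list alone, median 0.03, adjusted p = 0.327). Basement membrane genes fell, with Fn1 (−1.08 ± 0.05) and Hspg2 (−0.91 ± 0.07). The basement membrane list had 0 of 10 members that rose and 8 that fell (0 and 8 adjusted over the list alone, median −0.60, adjusted p = 1.2e-06, adjusted p = 0.0512 with an estimated correlation). Of 13128 genes 2122 rose and 3111 fell. The direct difference between siDGCR8 and siDROSHA passed for 7068 genes, 4603 higher and 2465 lower with siDGCR8. Ccn1 (0.95 ± 0.10) and Jun (0.28 ± 0.11) were higher with siDGCR8 and Myc (−1.5 ± 0.09) lower. Across 35 immediate-early genes, 17 rose and 6 fell (17 and 7 adjusted over the list alone, relative median 0.11, adjusted p = 0.555). Basement membrane genes were higher as a group. Across 10 basement membrane genes, 10 rose and 0 fell (10 and 0 adjusted over the list alone, relative median 0.82, adjusted p = 4.3e-09). Quantile scaling moved the median of all genes by −0.16 and the share higher from 65.1% to 48.1%.

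In human naive cells the same knockdowns asked whether species share the response. With siDGCR8, AP-1 targets rose, with the secreted SPP1 (62.7 ± 2.23 against 13.9 ± 2.23 CPM, 2.11 ± 0.12), PLAU (1.45 ± 0.11) and MMP9 (1.30 ± 0.22). In the AP-1 target list 11 of 11 members rose and 0 fell (11 and 0 adjusted over the list alone, relative median 0.94, adjusted p = 9.1e-08). Of SRF targets, ACTA1 (2.14 ± 0.16), CNN1 (1.88 ± 0.16) and TAGLN (1.52 ± 0.12) rose. Of 19 SRF target genes, 13 rose and 0 fell (16 and 0 adjusted over the list alone, relative median 0.30, adjusted p = 2.4e-08). The immediate-early genes FOSB (0.80 ± 0.18), CCN1 (0.72 ± 0.09), ATF3 (0.54 ± 0.11) and JUN (0.48 ± 0.08) rose, FOS (0.21 ± 0.25, adjusted p = 0.599) did not pass. In the immediate-early list 11 of 32 members rose and 3 fell (11 and 3 adjusted over the list alone, relative median 0.17, adjusted p = 0.161). The primed-state markers CD24 (2.12 ± 0.14) and FGF2 (1.62 ± 0.09) rose. In the primed list 4 of 8 members rose and 0 fell (4 and 0 adjusted over the list alone, relative median 0.76, adjusted p = 0.0122, adjusted p = 0.0591 with an estimated correlation). In the naive list 3 of 12 members rose and 7 fell (3 and 7 adjusted over the list alone, relative median −0.28, adjusted p = 0.0203, adjusted p = 0.0655 with an estimated correlation, adjusted p = 0.158 by quantile scaling). Of 14410 genes 2464 rose and 1392 fell, the median of all genes shifted by −0.11 under quantile scaling and the share that rose from 63.9% to 51.5%. Feeder-associated COL1A1 (0.52 ± 0.13) and COL5A1 (0.95 ± 0.14) rose in the same libraries, and nothing in the records says whether reads from the mouse feeder layer were removed.

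With siFLII added and DGCR8 less lowered, human actin and AP-1 groups fell again. ACTA1 (−1.89 ± 0.16), TAGLN (−1.38 ± 0.12) and PLAU (−1.29 ± 0.11) fell. The SRF target list had 0 of 19 members that rose and 15 that fell (0 and 15 adjusted over the list alone, median −0.30, adjusted p = 4.3e-14). Of 11 AP-1 target genes, 0 rose and 5 fell (0 and 8 adjusted over the list alone, median −0.48, adjusted p = 1.3e-06). Integrated stress genes fell, with VLDLR (−1.15 ± 0.11) and SESN2 (−0.96 ± 0.08). Of 14 integrated stress genes, 0 rose and 8 fell (0 and 11 adjusted over the list alone, median −0.29, adjusted p = 4.6e-09). Immediate-early FOSB (−0.88 ± 0.18), ATF3 (−0.67 ± 0.11) and CCN1 (−0.37 ± 0.09) fell, JUN (0.00 ± 0.08, adjusted p = 0.987) did not pass. Of 32 immediate-early genes, 0 rose and 5 fell (1 and 5 adjusted over the list alone, median −0.05, adjusted p = 0.0573). The list passed with a pseudocount of 0.1, without the filter, in a fit of both groups alone and without replicate 2 of the combined siRNAs (adjusted p 0.0471, 0.0274, 0.0464 and 0.0214), and the count without that library was 1232. Of 14410 genes 766 rose and 1108 fell. With siDROSHA, FOSB (1.70 ± 0.18), MAFF (1.68 ± 0.18), FOS (1.07 ± 0.25) and DUSP5 (1.23 ± 0.20), a nuclear ERK phosphatase, rose while JUN (−0.11 ± 0.08, adjusted p = 0.262) did not pass. The immediate-early list had 18 of 32 members that rose and 1 that fell (18 and 1 adjusted over the list alone, relative median 0.25, adjusted p = 0.0143, adjusted p = 0.0607 with an estimated correlation). Trophectoderm genes rose, with KRT7 (1.78 ± 0.11), TFAP2A (1.75 ± 0.11) and GATA3 (1.44 ± 0.06). Of 9 trophectoderm genes, 7 rose and 0 fell (8 and 0 adjusted over the list alone, relative median 0.86, adjusted p = 1.2e-05). Of 14410 genes 3877 rose and 2250 fell, the median of all genes shifted by −0.17 and the share that rose went from 63.3% to 46.3%. Both knockdowns differed directly for 5253 genes. Across 32 immediate-early genes, 3 rose and 10 fell (3 and 13 adjusted over the list alone, median −0.20, adjusted p = 0.170), with JUN (0.59 ± 0.08) higher and FOSB (−0.90 ± 0.18) lower under siDGCR8.

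**Figure D2:**
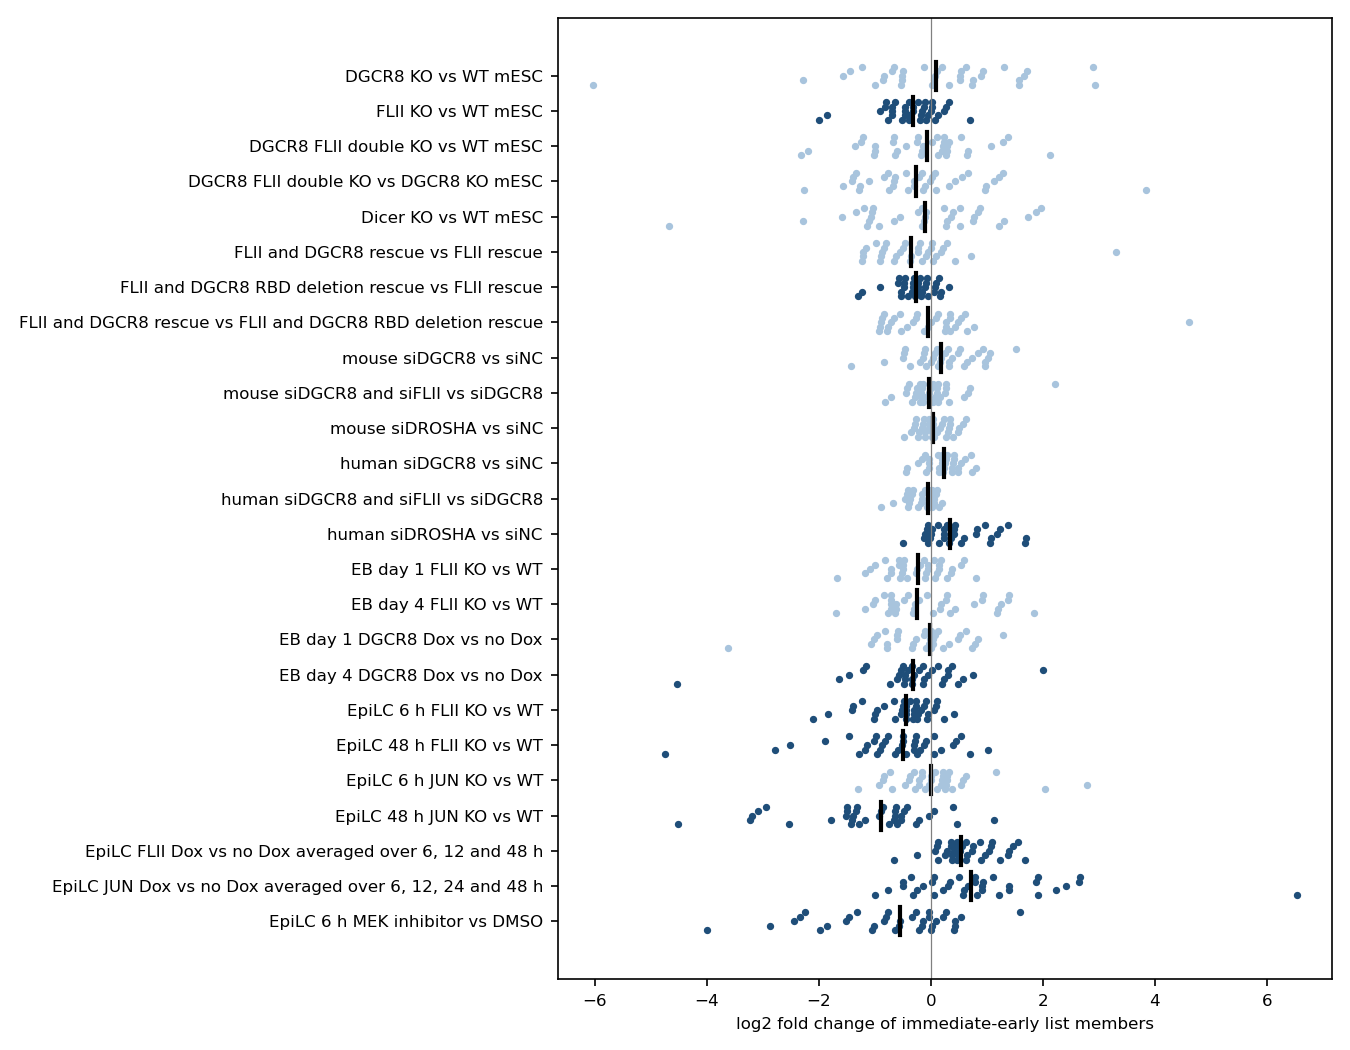
Log2 fold change of each measured member of the immediate-early list in every comparison of groups with n = 3 (points) and the list's median (bar), with passing comparisons by camera in a darker colour. The median reaches −0.89 in JUN KO EpiLCs at 48 h and 0.72 with JUN Dox.

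EpiLCs mimic the step from naive to formative state, and FLII KO cells were compared at 6 and 48 h to ask which immediate-early genes depend on FLII. At 6 h, Egr1 (3.33 ± 0.827 against 14.4 ± 0.487 CPM, −1.84 ± 0.14), Egr3 (−2.10 ± 0.16), Junb (−1.41 ± 0.13), Dusp5 (−1.38 ± 0.11) and Ier3 (−1.24 ± 0.21) were lower than in wild type, Fos (−0.08 ± 0.18, adjusted p = 0.798) and Jun (−0.06 ± 0.18, adjusted p = 0.856) did not pass. In the immediate-early list 2 of 37 members rose and 23 fell (2 and 25 adjusted over the list alone, median −0.44, adjusted p = 6.0e-11). ERK output genes fell with them, as Phlda1 (−1.14 ± 0.13) and Dusp6 (−0.63 ± 0.06) show. Of 12 ERK output genes, 1 rose and 7 fell (1 and 7 adjusted over the list alone, median −0.37, adjusted p = 8.1e-04). SRF targets fell, with Fhl2 (−1.19 ± 0.20) and Zyx (−0.80 ± 0.10). Across 17 SRF target genes, 1 rose and 7 fell (1 and 7 adjusted over the list alone, median −0.28, adjusted p = 0.00111). In total 1849 genes of 13981 rose and 1857 fell. The numbers paired the libraries here, and with replicate as a block the count was 4189 and the list's adjusted p 1.0e-10, while averaging replicates 2 and 3 gave 1812.

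At 48 h, Egr1 (2.00 ± 0.318 against 79.1 ± 6.21 CPM, −4.74 ± 0.14), Fos (0.883 ± 0.299 against 11.8 ± 0.219 CPM, −2.77 ± 0.18) and Fosb (−2.52 ± 0.22) were lower, with Jun (−0.96 ± 0.18), Zfp36 (−1.88 ± 0.12), which destabilises messenger RNAs, and Ccn1 (−0.97 ± 0.07). Of 37 immediate-early genes, 5 rose and 26 fell (5 and 26 adjusted over the list alone, relative median −0.60, adjusted p = 5.5e-10). The wild-type group of 48 h, shared by both knockouts, stood apart from the other controls at 48 h (DMSO n = 1). These had mean Egr1 at 2.47, 5.12 and 5.09 CPM, Fos at 0.790, 0.673 and 1.30 CPM, Jun at 5.11, 5.17 and 9.75 CPM and Ccn1 at 11.5, 9.85 and 32.0 CPM, all far below that group, so the lower levels at 48 h cannot be assigned to the genotype. Formative genes fell, with Fgf5 (1.40 ± 0.303 against 48.0 ± 3.94 CPM, −4.36 ± 0.15), Pou3f1 (−3.06 ± 0.15) and Dnmt3b (−2.0 ± 0.08). In the formative list 0 of 11 members rose and 10 fell (0 and 10 adjusted over the list alone, relative median −1.66, adjusted p = 2.8e-11). Naive genes were higher than in wild type, with Tbx3 (2.53 ± 0.12) and Tfcp2l1 (1.79 ± 0.09). In the naive list 11 of 14 members rose and 2 fell (11 and 2 adjusted over the list alone, relative median 1.11, adjusted p = 1.3e-05). Of 13981 genes 4260 rose and 2305 fell, the median of all genes shifted by −0.12 under quantile scaling and the share that rose from 64.9% to 50.9%. With that 48 h wild type, the FLII KO difference changed from 6 h for 4454 genes, 2893 up and 1561 down. Egr1 (−2.90 ± 0.20) and Fos (−2.69 ± 0.26) moved further down. In wild type Egr1 was 14.4 CPM at 6 h and 79.1 CPM at 48 h, whereas other controls were lower at 48 h. Of the immediate-early list 7 of 37 members rose and 11 fell (7 and 12 adjusted over the list alone, relative median −0.07, adjusted p = 0.101). Formative genes accounted for the strongest list. Of 11 formative genes, 0 rose and 9 fell (1 and 10 adjusted over the list alone, relative median −1.87, adjusted p = 1.1e-11). Without the libraries numbered 2 or 3 the count was 2845 or 2887, and with replicates 2 and 3 averaged 2857. The median of all genes shifted by −0.12 under quantile scaling and the share moving up from 65% to 50.7%.

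JUN KO cells went through the same course. At 6 h, Egr1 (62.6 ± 5.26 against 14.4 ± 0.487 CPM, 2.05 ± 0.14), Egr3 (2.80 ± 0.16) and Dusp5 (1.16 ± 0.11) were higher than in wild type while Ier5 (−1.30 ± 0.23), Jun (−0.93 ± 0.18) and Ier3 (−0.86 ± 0.21) were lower. The immediate-early list had 15 of 37 members that rose and 8 that fell (15 and 10 adjusted over the list alone, median 0.00, adjusted p = 0.538). ERK output genes rose, with Dusp4 (1.53 ± 0.09), Spred1 (1.07 ± 0.06) and Dusp6 (1.06 ± 0.06). The ERK output list had 8 of 12 members that rose and 2 that fell (8 and 2 adjusted over the list alone, median 0.46, adjusted p = 5.7e-04). The trophectoderm factor Tfap2a (3.34 ± 0.617 against 45.5 ± 4.87 CPM, −3.43 ± 0.18) and the keratins Krt18 (−2.46 ± 0.13) and Krt8 (−2.15 ± 0.10) were lower. The trophectoderm list had 1 of 9 members that rose and 7 that fell (1 and 7 adjusted over the list alone, median −0.90, adjusted p = 5.7e-04, adjusted p = 0.0816 with an estimated correlation). In total 3035 genes of 13981 rose and 3285 fell. At 48 h most early genes were lower than in the same deviating wild-type group, with Egr1 (2.51 ± 0.539 against 79.1 ± 6.21 CPM, −4.52 ± 0.14), Ccn1 (−3.19 ± 0.07), Fos (−3.08 ± 0.18), Fosb (−2.54 ± 0.22), Gadd45b (−2.95 ± 0.12) and Atf3 (−1.51 ± 0.23). Across 37 immediate-early genes, 3 rose and 31 fell (3 and 31 adjusted over the list alone, median −0.89, adjusted p = 3.8e-13). ERK output genes remained above wild type, with Spry4 (2.15 ± 0.07) and Etv4 (1.66 ± 0.07). Across 12 ERK output genes, 9 rose and 1 fell (9 and 1 adjusted over the list alone, median 0.71, adjusted p = 4.7e-05). Fgf5 (−3.85 ± 0.15) and Otx2 (−1.95 ± 0.12) fell in the formative list. The formative list had 3 of 11 members that rose and 7 that fell (3 and 7 adjusted over the list alone, median −0.70, adjusted p = 0.0239, adjusted p = 0.104 with an estimated correlation). Of 13981 genes 3164 rose and 3240 fell. The change between 6 and 48 h was itself tested and passed for 4496 genes, with Egr1 (−6.57 ± 0.20), Ccn1 (−3.82 ± 0.10) and Gadd45b (−2.66 ± 0.17) moving down, again against that 48 h wild-type group. In the immediate-early list 2 of 37 members rose and 25 fell (2 and 26 adjusted over the list alone, median −0.89, adjusted p = 5.9e-14). Without the libraries numbered 2 or 3 the count was 2762 or 2734, and with replicates 2 and 3 averaged 2600.

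**Figure D3:**
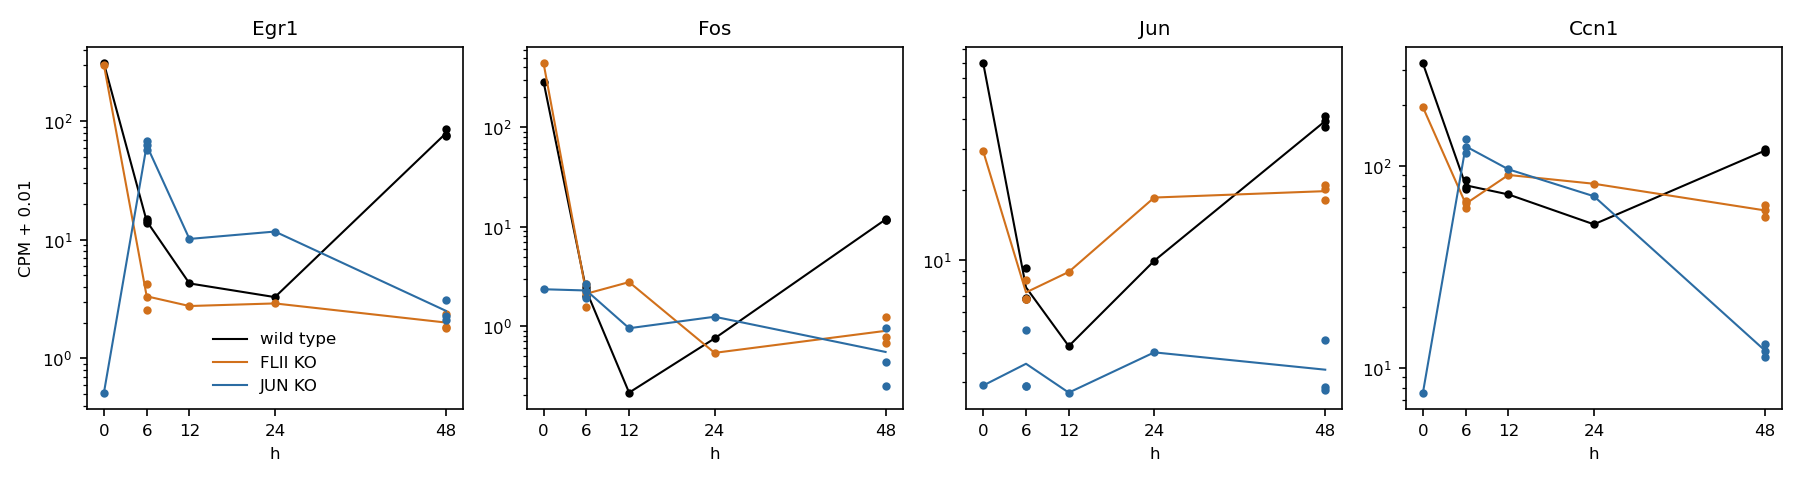
CPM of Egr1, Fos, Jun and Ccn1 (log axis, 0.01 added) against hours of EpiLC differentiation in wild-type, FLII KO and JUN KO cells, 1 point per library and a line through the means, with n = 3 at 6 and 48 h and n = 1 at 0, 12 and 24 h. At 48 h wild-type libraries lie above both knockouts for all 4 genes, and above the 48 h controls of the other experiments, which are not drawn.

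Raising FLII during EpiLC differentiation asked the converse question, with the Dox effect averaged over 6, 12 and 48 h (n = 9 per arm). Ccn1 (1.69 ± 0.07), Atf3 (1.56 ± 0.17), Jun (1.47 ± 0.11), Klf6 (1.38 ± 0.09), Junb (0.97 ± 0.08) and Egr1 (0.88 ± 0.12) rose. Of 36 immediate-early genes, 29 rose and 2 fell (29 and 2 adjusted over the list alone, relative median 0.42, adjusted p = 1.7e-06). Trophectoderm genes rose, with Krt8 (2.12 ± 0.06), Cdx2 (1.97 ± 0.17) and Krt7 (1.92 ± 0.11). Across 9 trophectoderm genes, 8 rose and 0 fell (8 and 0 adjusted over the list alone, relative median 1.41, adjusted p = 3.4e-06). The AP-1 targets Plaur (1.86 ± 0.06), Hbegf (1.79 ± 0.06), a ligand of the EGF receptor, and Spp1 (1.42 ± 0.06) rose. The AP-1 target list had 8 of 8 members that rose and 0 that fell (8 and 0 adjusted over the list alone, relative median 0.60, adjusted p = 9.6e-06). SRF targets rose, with Fhl2 (1.70 ± 0.13) and Zyx (1.11 ± 0.08). In the SRF target list 16 of 17 members rose and 0 fell (16 and 0 adjusted over the list alone, relative median 0.64, adjusted p = 9.6e-06). Otx2 (−1.52 ± 0.08) fell. Across 11 formative genes, 1 rose and 9 fell (1 and 9 adjusted over the list alone, relative median −0.59, adjusted p = 3.4e-06). Of 13733 genes 5125 rose and 2013 fell, and quantile scaling moved the median of all genes by −0.17 and the share that rose from 71.8% to 46.9%. That shift came from 12 h, where the median of all genes was 0.32 against 0.03 at 6 h and 0.02 at 48 h, and the count was 4353 with 12 h left out. The immediate-early median was 0.58 at 6 h, 0.42 at 12 h and 0.51 at 48 h relative to all genes, each past the threshold. The pair at 24 h (n = 1 each) lay otherwise, with Egr1 at 2.91 against 10.7 CPM, Junb at 18.6 against 26.6 CPM and a list median of 0.07. With the libraries numbered 2 or 3 left out the count was 4432 or 3967, and with replicates 2 and 3 averaged 4542.

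JUN was raised over 6, 12, 24 and 48 h in the same way (n = 12 per arm). The ERK phosphatases Dusp5 (2.66 ± 0.07) and Dusp2 (2.64 ± 0.12), the AP-1 subunit Fosl1 (2.41 ± 0.12), Dusp1 (2.23 ± 0.04) and Atf3 (1.89 ± 0.12) rose, Egr1 (−0.76 ± 0.13) and Fos (−0.49 ± 0.14) fell, and of the immediate-early list, which holds Jun (6.54 ± 0.07) itself, 25 of 36 members rose and 7 fell (25 and 7 adjusted over the list alone, median 0.72, adjusted p = 4.7e-07). By time, Atf3 rose at 6, 12 and 24 h but fell at 48 h (−0.59 ± 0.24), Egr1 did not pass at 12 h (0.31 ± 0.25) and Fos at neither 12 h (0.07 ± 0.29) nor 48 h (−0.26 ± 0.29). AP-1 targets rose, with Plau (3.05 ± 0.10), Cd44 (2.65 ± 0.14) and Hbegf (1.77 ± 0.05). Across 10 AP-1 target genes, 9 rose and 1 fell (9 and 1 adjusted over the list alone, median 1.34, adjusted p = 6.7e-06). Trophectoderm genes rose, with Krt18 (3.13 ± 0.06), Krt8 (3.03 ± 0.04) and Hand1 (2.58 ± 0.12). In the trophectoderm list 9 of 10 members rose and 0 fell (10 and 0 adjusted over the list alone, median 0.86, adjusted p = 6.7e-06). Otx2 (−2.53 ± 0.07) and Lin28a (−2.84 ± 0.05) fell. In the formative list 0 of 11 members rose and 10 fell (0 and 10 adjusted over the list alone, median −1.03, adjusted p = 9.4e-07). Naive genes fell on average, with Klf4 (−1.29 ± 0.06) and Nanog (−1.20 ± 0.04). Of 14 naive genes, 1 rose and 11 fell (1 and 11 adjusted over the list alone, median −0.83, adjusted p = 9.4e-07), but this list's median was −1.29 at 6 h, −1.67 at 12 h, −0.98 at 24 h and 1.26 at 48 h, where it had passed upward. Of 13911 genes 4255 rose and 4237 fell.

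PD0325901 at 1 µM for 6 h of EpiLC differentiation asked which early genes need MEK. Egr1 (0.917 ± 0.426 against 28.9 ± 0.267 CPM, −3.99 ± 0.19), Myc (−2.87 ± 0.11), Fosl1 (−2.44 ± 0.25), Dusp5 (−1.99 ± 0.13) and Junb (−1.86 ± 0.10) fell, Jun (0.43 ± 0.15) rose, Fos (0.10 ± 0.30, adjusted p = 0.820) did not pass. The immediate-early list had 7 of 35 members that rose and 20 that fell (7 and 22 adjusted over the list alone, median −0.55, adjusted p = 2.6e-05, adjusted p = 0.0611 with an estimated correlation). The ERK feedback genes Spry4 (3.37 ± 0.199 against 135 ± 6.31 CPM, −4.96 ± 0.11), Phlda1 (−4.33 ± 0.10), Etv4 (−2.43 ± 0.07) and Dusp4 (−2.26 ± 0.11) fell. In the ERK output list 1 of 12 members rose and 11 fell (1 and 11 adjusted over the list alone, median −1.15, adjusted p = 4.4e-11, adjusted p = 0.0611 with an estimated correlation). Naive genes rose, with Prdm14 (1.79 ± 0.10) and Klf2 (1.61 ± 0.05). The naive list had 11 of 14 members that rose and 2 that fell (11 and 2 adjusted over the list alone, median 0.82, adjusted p = 3.8e-08, adjusted p = 0.0611 with an estimated correlation). The AP-1 targets Plaur (−3.74 ± 0.07) and Hbegf (−2.47 ± 0.10) fell. In the AP-1 target list 1 of 8 members rose and 6 fell (1 and 7 adjusted over the list alone, median −1.35, adjusted p = 7.4e-06, adjusted p = 0.0611 with an estimated correlation). Of 12620 genes 2563 rose and 2536 fell.

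Embryoid bodies asked how FLII KO cells leave the stem cell state outside adherent culture. At day 1, extraembryonic endoderm genes were lower, with Cubn (14.7 ± 2.26 against 253 ± 2.82 CPM, −4.03 ± 0.20), Dab2 (−2.55 ± 0.14) and Gata6 (−2.17 ± 0.23). The extraembryonic endoderm list had 0 of 14 members that rose and 11 that fell (0 and 12 adjusted over the list alone, relative median −1.68, adjusted p = 1.4e-07). Naive and ERK output genes were lower too, with Tbx3 (−2.03 ± 0.14), Tfcp2l1 (−1.83 ± 0.16), Etv4 (−1.70 ± 0.13) and Spry4 (−1.23 ± 0.11). Across 14 naive genes, 1 rose and 12 fell (1 and 12 adjusted over the list alone, relative median −0.93, adjusted p = 1.0e-05). Of 12 ERK output genes, 0 rose and 10 fell (0 and 11 adjusted over the list alone, relative median −0.96, adjusted p = 2.5e-06, adjusted p = 0.0979 with an estimated correlation). Sgk1 (−1.17 ± 0.14), Fos (−0.71 ± 0.18) and Egr1 (−0.70 ± 0.13) fell, Jun (0.05 ± 0.14, adjusted p = 0.788) did not pass. Across 36 immediate-early genes, 5 rose and 16 fell (6 and 17 adjusted over the list alone, relative median −0.15, adjusted p = 0.147). Of 14723 genes 2596 rose and 3851 fell, and the median of all genes shifted by 0.10 under quantile scaling and the share that rose from 40.3% to 51.1%. The count was 3044 with replicates 2 and 3 averaged.

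At day 4, genes that mark 2-cell-like cells, a rare state resembling the early embryo after genome activation, were far higher, with Zscan4d (109 ± 2.17 against 2.71 ± 0.655 CPM, 4.91 ± 0.18), Usp17la (4.47 ± 0.18) and Zscan4c (4.38 ± 0.16). In the 2-cell-like list 10 of 10 members rose and 0 fell (10 and 0 adjusted over the list alone, median 3.80, adjusted p = 6.4e-13). Dppa3 (70.3 ± 1.77 against 5.50 ± 1.12 CPM, 3.47 ± 0.14) rose with them. Jun (−0.71 ± 0.14), Fos (−0.65 ± 0.18), Egr1 (−0.63 ± 0.13) and Ier3 (−1.69 ± 0.15) fell and Atf3 (1.20 ± 0.15), Plk3 (1.84 ± 0.12) and Ccn1 (0.91 ± 0.12) rose, so that of the immediate-early list 11 of 36 members rose and 15 fell (12 and 16 adjusted over the list alone, median −0.25, adjusted p = 0.880). Of 14723 genes 3068 rose and 3319 fell, and 3480 changed with replicates 2 and 3 averaged. Wild-type replicate 1 stood apart, by a root mean square log2 difference of 0.63 and 0.62 from the others, which differed by 0.12, and without it 9152 genes changed. The effect differed between days for 3792 genes, among which Zscan4d (4.99 ± 0.26) moved up. Of 10 2-cell-like genes, 10 rose and 0 fell (10 and 0 adjusted over the list alone, median 3.86, adjusted p = 1.8e-13). Without the libraries numbered 1, 2 or 3 the count was 5872, 1414 or 720, and 1533 with replicates 2 and 3 averaged.

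**Figure D4:**
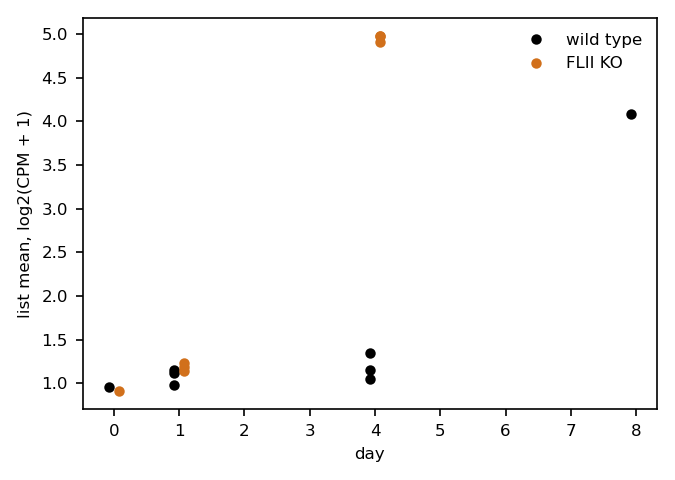
Mean log2(CPM + 1) of the 10 genes of the 2-cell-like list in each library of wild-type and FLII KO embryoid bodies against day, 1 point per library. FLII KO libraries at day 4 lie between 4.91 and 4.98 against 1.05 to 1.35 in wild type, and the single wild-type library of day 8 lies at 4.08.

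Dox in the DGCR8 line was the converse test in embryoid bodies, although Dgcr8 stood at 103 ± 7.68 against 74.9 ± 2.60 CPM at day 1 and no higher than its control at day 4. Whether the day 4 changes follow from its earlier level was not tested. Nor can effects of Dox itself be told apart from those of DGCR8, without a Dox-treated line lacking the transgene. At day 1, glycolysis genes fell, with Ldha (278 ± 5.90 against 1019 ± 78.6 CPM, −1.87 ± 0.07) and Slc2a1 (−1.77 ± 0.06), a glucose transporter. Of 14 glycolysis genes, 0 rose and 13 fell (0 and 13 adjusted over the list alone, median −0.70, adjusted p = 5.9e-14). Integrated stress genes rose, with Chac1 (71.5 ± 7.12 against 5.37 ± 1.01 CPM, 3.52 ± 0.12), Trib3 (2.5 ± 0.12) and Ddit3 (2.24 ± 0.11). The integrated stress list had 10 of 14 members that rose and 2 that fell (10 and 2 adjusted over the list alone, median 1.36, adjusted p = 3.6e-08). Ier3 (2.45 ± 0.40 against 41.4 ± 5.27 CPM, −3.62 ± 0.16), Fos (−0.96 ± 0.21), Egr1 (−0.79 ± 0.14) and Dusp1 (−1.01 ± 0.09) fell, Atf3 (1.30 ± 0.14) and Jun (0.79 ± 0.13) rose. In the immediate-early list 8 of 34 members rose and 12 fell (9 and 13 adjusted over the list alone, median −0.02, adjusted p = 0.268), and the median turned to 0.01 without Dox replicate 1. Of 14169 genes 2354 rose and 2338 fell. The numbers paired the libraries on both days, and with replicate as a block the day 1 count was 6700, while averaging replicates 2 and 3 gave 2896.

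At day 4, with Dgcr8 not raised, extraembryonic endoderm genes rose, with Cubn (3402 ± 25.9 against 606 ± 60.1 CPM, 2.49 ± 0.07), Amn (2.35 ± 0.17) and Pdgfra (1.89 ± 0.09). Across 14 extraembryonic endoderm genes, 14 rose and 0 fell (14 and 0 adjusted over the list alone, median 1.62, adjusted p = 1.6e-16). Basement membrane genes rose, with Col4a2 (1.94 ± 0.06) and Sparc (1.64 ± 0.06). In the basement membrane list 7 of 10 members rose and 0 fell (7 and 0 adjusted over the list alone, median 0.97, adjusted p = 9.8e-07). Ier3 (2.35 ± 0.817 against 74.7 ± 4.02 CPM, −4.53 ± 0.16), Dusp1 (−1.65 ± 0.09), Fos (−1.46 ± 0.21) and Egr1 (−1.21 ± 0.14) fell and Atf3 (2.00 ± 0.14) rose. Of 34 immediate-early genes, 7 rose and 17 fell (7 and 18 adjusted over the list alone, median −0.32, adjusted p = 0.0423, adjusted p = 0.0929 with an estimated correlation). The 2-cell-like genes Zscan4d (−3.27 ± 0.19) and Zscan4c (−3.25 ± 0.21) fell. The 2-cell-like list had 0 of 6 members that rose and 6 that fell (0 and 6 adjusted over the list alone, median −2.10, adjusted p = 5.4e-06, adjusted p = 0.0531 with an estimated correlation). Of 14169 genes 2849 rose and 3323 fell. With replicate as a block, since the numbers paired the libraries, the immediate-early list's adjusted p was 0.0538, with a pseudocount of 0.1 0.0505, and without Dox replicate 1 or no-Dox replicate 1 0.0563 or 0.0613. The effect differed between days for 2778 genes, or 4913 with replicate as a block, 1356 with replicates 2 and 3 averaged, and 975 or 811 without the libraries numbered 2 or 3. Extraembryonic endoderm genes moved further up, with Cubn (2.23 ± 0.10). In the extraembryonic endoderm list 13 of 14 members rose and 0 fell (14 and 0 adjusted over the list alone, median 1.31, adjusted p = 1.4e-18).

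Genes of whole chromosomes lay apart between most lines, though by no more than 0.1 for any autosome in the FLII and DGCR8 rescue against the FLII rescue. In JUN KO EpiLCs at 48 h the median of chromosome 14 genes lay 0.35 from that of all genes and that of chromosome 19 genes −0.19, while in FLII KO EpiLCs chromosome 14 lay at −0.21 and in FLII KO embryoid bodies of day 4 at −0.35. Chromosome 8 lay at −0.42 in Dicer KO cells and chromosome 3 at 0.28 in the RBD-deletion rescue against the FLII rescue. With every chromosome shifted by over 0.1 left out, the immediate-early median at 48 h, without reference to all genes, was −0.51 in FLII KO (−0.51 with them) and −0.75 in JUN KO cells (−0.89 with them), both with an adjusted p under 0.05. No autosome was shifted by over 0.1 in any mouse comparison of Dox, siRNA or inhibitor with its control.

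**Figure D5:**
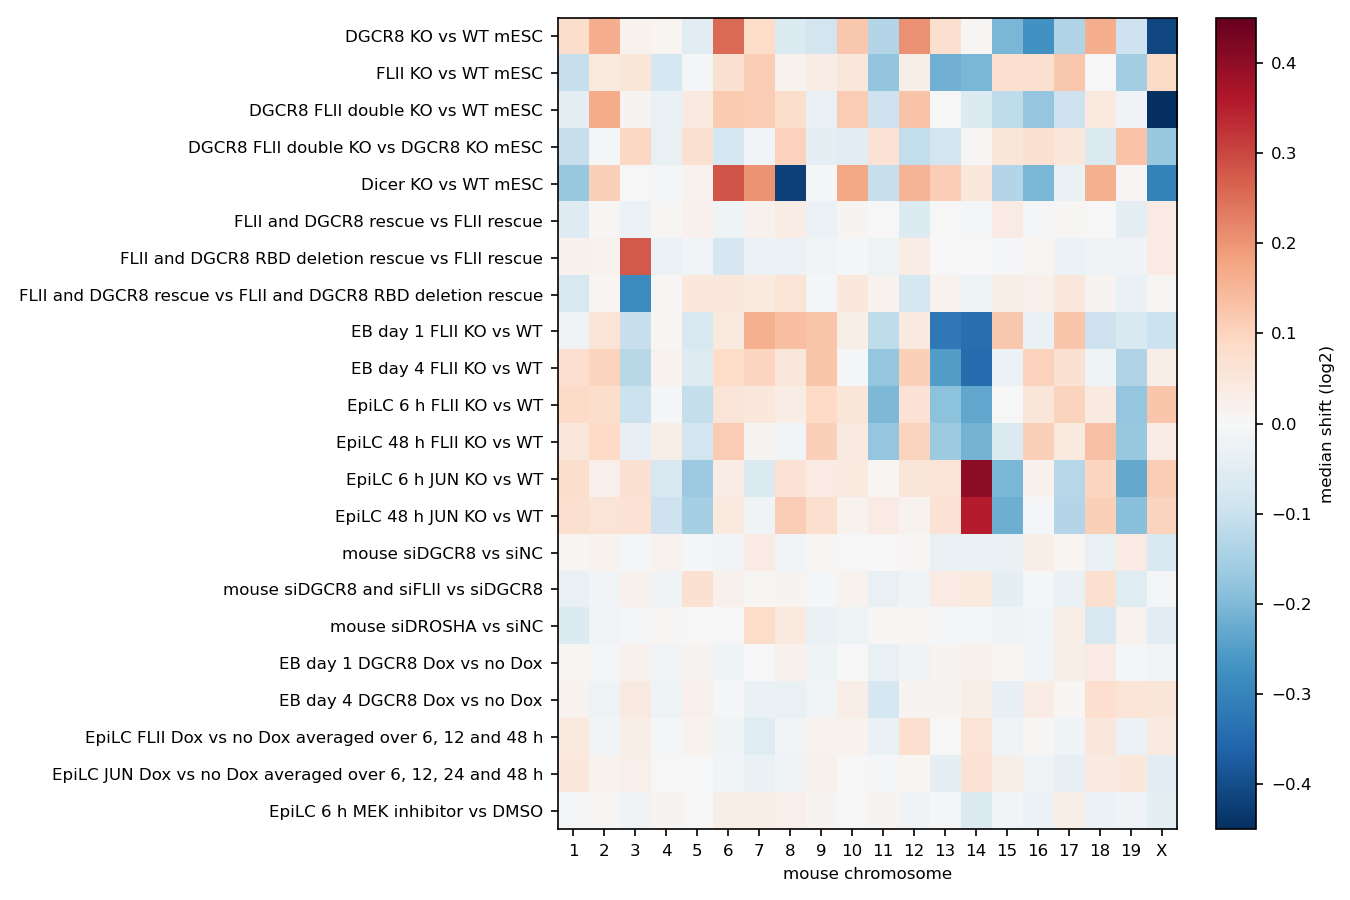
Median log2 fold change of the genes of each mouse chromosome minus that of all genes, for every comparison of mouse groups with n = 3 (colour scale). Comparisons between lines stand above those within a line, and the shifts of chromosome 14 in JUN KO and FLII KO cells have opposite signs.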

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

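The tests on 2-cell-like genes, the counts over other splits of the samples and the spread added to the bound for chromosome 14 in FLII KO EpiLCs were chosen only after the results were seen, and so was the wording of the knockdown tests, whose explanation was first a lost or weaker knockdown and was narrowed to a loss to the extent the transcript shows. Interaction tests passed for 3749 genes (loss of FLII with and without DGCR8). Day 4 against day 1 gave 3792 (FLII KO embryoid bodies) and 2778 (DGCR8 Dox). EpiLCs at 48 against 6 h gave 4454 (FLII KO) and 4496 (JUN KO), both with the deviating 48 h wild type. Neither is assignable to genotype.

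With 3 samples against 3 there are 10 splits, too few for a share under 0.05. In these comparisons the real split gave between 534 and 7479 genes and the highest of the other splits 0, or 1 in human combined siRNAs against siDGCR8 and in FLII KO EpiLCs at 6 h. FLII KO against wild-type mESCs gave 1 gene, as did 1 other split, so that 2 of 10 splits gave as many. Among 100 splits, the real one alone reached 7138 genes for FLII Dox (highest other 4374) and 8492 for JUN Dox (4423). This share, 0.01, assumes independent replicates. For the 5 interactions, a split that exchanges labels in 1 background or time only turns the difference of 2 effects into their sum, so the effects themselves fix the counts and the splits decide nothing. As many genes as the real split came from 6 of 100 splits for loss of FLII with and without DGCR8 (highest other 5509), 2 for FLII KO in embryoid bodies (5165), 3 for DGCR8 Dox (7000), 3 for FLII KO in EpiLCs (6542) and 1 for JUN KO in EpiLCs (3509).

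Genes on chromosome 14 lay higher in JUN KO EpiLCs and lower in FLII KO EpiLCs than in wild type. In JUN KO cells each of 4 equal segments of the chromosome was shifted by at least 0.33, 76.0% of its genes lay above the median of all genes, and the smallest of the 3 same-numbered differences was 0.33, values that argue against a few strong genes or 1 library as the source. A different number of copies of chromosome 14 in part or all of the JUN KO cells may account for this shift. In FLII KO cells 71.5% of genes lay below and the smallest same-numbered difference was −0.18, but the segment with the smallest shift lay at −0.087 with a standard error of 0.05, so a change of the whole chromosome cannot be told apart from a regional one. Whether either shift follows from the genotype or from the history of the line was not tested.

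Genes of the 2-cell-like list lay far higher in FLII KO embryoid bodies at day 4, in a family with many similar copies. Zfp352, the member taken as single copy, had a log2 fold change of 3.82, which argues against reads shared between copies. The lowest FLII KO library exceeded the highest wild-type library by 3.56 in the list's mean, so 1 library is not the source. The single wild-type library of day 8 had a list mean of 4.08, and an earlier or later course of the same program in FLII KO bodies may therefore be as good an account as an effect of FLII on these genes.

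Dgcr8 was not lowered in mouse cells with siDGCR8 and siFLII combined, and only in part in human cells. If the knockdown were lost to that extent, genes that siDGCR8 moved would return as far as Dgcr8, which kept −0.04 of its siDGCR8 difference in mouse cells. Mouse microRNA host transcripts kept 0.754 of theirs, from 0.659 to 0.871 by library, which argues against a complete loss. All 4263 genes changed by siDGCR8 kept only 0.224 (0.213 to 0.244), the miR-290 and miR-302 targets 0.150, immediate-early genes 0.729 and glycolysis genes 0.918, so a weaker knockdown stays open. Human host transcripts, only 3 genes, kept 0.456 with libraries from 0.029 to 0.580, and DGCR8 0.585, so a weaker knockdown may account for part of the difference that was read as an effect of FLII there.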

How the results depend on the processing

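Averaging replicates 2 and 3, the term for even read numbers, edgeR and leaving out chromosomes or times were chosen after the results were seen. Of 4541 alternative values, 4365 kept direction and side of the threshold, or a count within 1.5 times. These were 343 gene counts, 277 immediate-early medians and 3745 values of named genes, most picked for passing, which raises that share. Of named genes 77 values missed the threshold, 5 came past it and 20 turned. List medians stand here without reference to all genes. Genes changed in FLII KO mESCs were 8 without the filter and 0 with a pseudocount of 0.1, the replicate block or edgeR. The RBD-deletion rescue gave 272 without the filter and double KO against DGCR8 KO cells 4675 with the term for even read numbers. With replicates 2 and 3 averaged, 11 of 23 counts moved, to 2447 for mouse siDGCR8 and 3619 for the combined siRNAs. That setting gave 3044 and 3480 for FLII KO embryoid bodies at days 1 and 4, 2896 for DGCR8 Dox at day 1, 1812 for FLII KO EpiLCs at 6 h and 4542 for FLII Dox. Interactions then gave 1533 (FLII KO bodies), 1356 (DGCR8 Dox), 2857 (FLII KO EpiLCs) and 2600 (JUN KO EpiLCs). FLII Dox without 12 h gave 4353 genes. With the replicate block the DGCR8 Dox interaction gave 4913. The immediate-early median turned to −0.030 in DGCR8 KO by quantile scaling, 0.063 in double KO against wild type without shifted chromosomes and 0.18 in Dicer KO with the term for even read numbers. It turned to 0.025 without the filter and 0.0085 without shifted chromosomes between the whole and RBD-deletion rescues, and 0.062 by quantile scaling and 0.0031 with replicates averaged in mouse combined siRNAs. It passed at 0.12 without the filter and 0.097 by quantile scaling in mouse siDGCR8, and at −0.066 with a pseudocount of 0.1, −0.048 without the filter and −0.060 in a fit of both groups alone in human combined siRNAs. In DGCR8 Dox at day 4 it missed the threshold at −0.33 with a pseudocount of 0.1 and −0.32 with the replicate block.

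Leaving out each replicate in turn gave ranges of counts of 0 to 56 for FLII KO mESCs, 123 to 484 for the RBD-deletion rescue, 1232 to 1593 for human combined siRNAs and 3967 to 8778 for FLII Dox. In the interactions counts ran over 0 to 5688 (FLII loss by DGCR8 background), 720 to 5872 (FLII KO bodies), 811 to 3720 (DGCR8 Dox), 2845 to 4391 (FLII KO EpiLCs) and 2734 to 3698 (JUN KO EpiLCs). Immediate-early medians ranged over −0.080 to 0.39 in DGCR8 KO (0.094 with all), −0.40 to −0.12 in FLII KO, −0.12 to 0.27 in double KO against wild type and −0.16 to 0.20 in Dicer KO. They ranged over −0.39 to −0.27 in the whole (−0.35 with all) and −0.41 to −0.11 in the RBD-deletion rescue against FLII rescue, −0.22 to 0.0058 between these rescues and 0.16 to 0.30 in mouse siDGCR8 (0.18 with all). The ranges were −0.13 to 0.0028 in mouse (−0.030 with all) and −0.15 to −0.043 in human combined siRNAs, and −0.058 to 0.0081 at day 1 and −0.30 to −0.26 at day 4 of DGCR8 Dox. Named genes that turned had missed the threshold. Jun was −0.15 in double KO against wild type with the term for even read numbers, Fos 5.7e-04 in mouse combined siRNAs and FOS −7.6e−04 in human siDGCR8 by quantile scaling. With replicates averaged JUN was −0.0048 in human combined siRNAs, Fos 0.011 and Jun 0.018 in FLII KO EpiLCs at 6 h and Fos −0.062 with MEK inhibitor. Without 1 replicate, Jun ranged over −0.084 to 0.51 in double KO against wild type, −0.093 to 0.19 in FLII KO bodies at day 1 and −0.14 to 0.070 in FLII KO EpiLCs at 6 h, and JUN over −0.037 to 0.029 in human combined siRNAs. Likewise Fos ranged over −0.21 to 0.057 in FLII KO EpiLCs at 6 h, −0.33 to 0.44 with MEK inhibitor, −0.68 to 0.12 between the rescues, −0.35 to 0.13 in mouse combined siRNAs and −0.45 to 0.11 in mouse siDROSHA. The cause of these changes was not tested. edgeR was not run for FLII KO embryoid bodies, for DGCR8 Dox at day 1 and the interactions of both, or for FLII Dox, where too few libraries had recovered reads.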

Other observations

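Single libraries were compared without a test. FLII rescue against the single double KO library without rescue had medians of 2.15 (trophectoderm), 0.96 (SRF targets) and 0.27 (immediate-early). Percentiles among matched random lists were 100, 100 and 98.5. Ccn1 was 112 against 24.9, Atf3 11.4 against 3.67, Jun 34.8 against 31.2 and Junb 52.0 against 49.1 CPM. Double KO mESCs had Jun at 14.6 ± 7.07 CPM. At 0 h of EpiLC differentiation, JUN KO cells had an immediate-early median of −1.03 (percentile 0), Fos at 2.33 against 284 CPM and Egr1 at 0.504 against 307 CPM. This wild-type library itself stood apart from other controls at 0 h, which had Fos at 1.24, 1.76 and 2.37 CPM and Egr1 at 8.5, 0.830 and 0 CPM, while the FLII KO library had 437 and 297 CPM and the FLII line with Dox 186 and 385 CPM, so the difference cannot be assigned to JUN. With JUN Dox in 2i/Lif against the single library without Dox, of 0 h, the trophectoderm median reached 1.46, 2.35, 3.43 and 2.44 at 6, 12, 24 and 48 h, and the immediate-early median 0.89, 0.93, 1.05 and 0.37. The 12 h group held 3 libraries, of which replicate 1 differed from the others by a root mean square of 0.85 and 0.78 and these from each other by 0.24.

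In wild-type embryoid bodies the single day 8 library against day 0 had a naive pluripotency median of −2.56, a formative median of 2.59, an extraembryonic endoderm median of 1.83 and an immediate-early median of 0.87 (percentiles 0, 100, 100 and 100). PD0325901 at 1, 5 and 25 µM gave day 1 embryoid bodies an ERK output median of −0.76, −1.58 and −1.46, a naive median of 1.15, 1.61 and 1.70, and an immediate-early median of 0.37, 0.41 and 0.34. Within that list Egr1 stood at 0.360, 0.320 and 0.45 CPM against 8.12 without inhibitor, and Jun at 29.1, 21.9 and 23.3 against 3.57 CPM.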
